A study of Mus musculus with 18 samples.

How the data were processed

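Liver RNA of 18 mouse newborns was measured on 18 Agilent 4x44K whole-genome arrays, 1 pup per array. Per the labels, time-mated C57BL/6BomTac dams received carbon black Printex 90, a nanosized soot-like particle, or the vehicle (water) by intratracheal instillation. There were 4 instillations, on days 7, 10, 15 and 18 of gestation. The high dose was 67 µg per instillation and 268 µg in total, and the pups were killed on postnatal day 2. Each array held Cy5-labelled liver RNA and Cy3-labelled universal mouse reference RNA. The labels give 5 control females, 4 high-exposure females, 5 control males and 4 high-exposure males. They do not state which pups were littermates, so litter could not be put into any model. The lower doses and the dams named in the series description were not analysed here.

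Per the file headers, the scanner files came from Agilent Feature Extraction 10.1.1.1 and hold spot and local background signals as intensity, and also background-subtracted and dye-normalized intensity. Per the file headers, the same files give the ratio of both channels as log10 of Cy5 over Cy3. The series value table deposited by the authors holds log2 of Cy5 over Cy3, normalized within each array by a method that the labels do not name. This was checked on the values: on each array the table correlated across probes at 0.991 to 0.995 with log2 ratios of the median signals after loess, with slopes of 0.981 to 0.989, and its array medians lay between -0.0491 and -0.0365. The table has 45220 entries and each scanner file 45018 spots.

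The analysis started from the scanner files. The plan named the mean spot signals, but the deposited files hold median signals, which were used instead. Background was corrected with normexp (offset 50) and ratios were normalized by loess within each array in limma 3.58.1 under R 4.3.3. Control spots and spots marked as non-uniform or as population outliers in either channel had weight 0 in loess and were then set to missing. Spots of 1 probe were averaged, and a probe was kept when Cy5 lay well above background on at least 4 of the 18 arrays, which left 26158 of 41174 probes. Gene symbols came from matching the probes' RefSeq identifiers to a reference table of the mouse genome build GRCm38.p6, which named 56.8% of the probes. A gene was represented by its probe with the highest mean Cy5 signal. This gave 21062 transcripts tested, of which 12535 were named genes and 8527 were unnamed probes. Genomic positions were not used here.

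Precision is limited by the number of arrays. Array medians of the Cy5 signal were 130 to 153, against local backgrounds of 79 to 82.5. Between 55.4% and 68.5% of the probes on an array had Cy5 well above background. The arrays lay on 5 slides and were scanned on 3 days. On each slide, position 1 held a control male, position 2 a control female and positions 3 and 4 the high-exposure pups. Array position is therefore tied to exposure, and in controls also to the labelled sex, whereas for each sex 4 slides held both exposures.

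Group differences were tested with limma: 1 mean per group over all 18 arrays, contrasts, moderated statistics (eBayes), 2-sided, Benjamini-Hochberg over all 21062 transcripts, with a threshold of adjusted p 0.05. The comparisons were high against control in females, in males and averaged over both sexes, the difference of the exposure effect between the sexes (female minus male), and male against female in controls and in high-exposure pups. All groups shared 1 estimate of the spread per gene. A list of 49 gene sets covering liver functions, stress and hormone responses, blood and immune cells, liver cell types and neighbouring tissue was fixed before the data were examined, as were the comparisons, the filters and the rule for named genes. Each list was tested against all other genes with camera (preset correlation 0.01), adjusted over the 49 lists. The same test with an estimated correlation and the self-contained test fry were run beside it. List values are medians of log2 differences over the measured members. Per-library list values are medians after subtracting the mean of the control libraries.

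The genes named per exposure comparison are the 12 highest and the 12 lowest log2 differences among those past the threshold. With fewer than 20 past it, genes with the smallest unadjusted p were added up to 20 and are given as values only. For the difference between the sexes, the 6 genes with the smallest p are named. For the sex comparisons the fixed sex-linked genes are named, and for each list up to 4 members with the smallest p. The fit was tested on simulated data in which 200 transcripts were shifted in the high-exposure females, in 5 runs. It recovered 63.9% of changes of 0.5, 92.8% of changes of 1 and 99.1% of changes of 2 (log2), with a mean of 10.4 false calls. The simulated noise was independent between genes and had the same spread in all groups. The real high females varied more than the other groups, so these rates need not hold for the real comparison.

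Alternatives covered background correction, normalization, probe filters and probe rules, array weights, variance models, thresholds, and leaving out each array in turn. Slide was also fitted as a fixed or random block. The number in the sample titles, here called the pup number, was fitted as a random block. What this number stands for is not stated in the labels. A further 4 alternatives, each leaving out several named libraries, were chosen after seeing the data. The Cy3 reference channel was tested with the same model after quantile normalization as a control. Plots were drawn with matplotlib 3.10.9.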

Results

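Gene expression was measured in the liver of 2-day-old mouse pups whose mothers had received 268 µg of carbon black Printex 90 or vehicle through the airways during pregnancy. The groups were 5 control females, 4 high-exposure females, 5 control males and 4 high-exposure males, with 1 array per pup. Values are log2 ratios of liver over a common reference RNA, and differences are high minus control unless stated. Median Cy5 signals per array were 130 to 153 over local backgrounds of 79 to 82.5, so dim transcripts were measured close to background. On each slide the control pups lay in positions 1 and 2 and the exposed pups in positions 3 and 4, so no difference between exposures is free of array position.

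Several libraries stood apart from their groups. Exocrine pancreas genes such as Prss3, Cela3b and Cpb1, which encode digestive enzymes, had list medians of 2.76 in high female 8 and 1.94 in high female 13, against -0.25 to 0.69 in the 10 control libraries. Skeletal muscle genes such as Acta1, Myl1 and Tnnc2, parts of the contractile apparatus, had a list median of 2.80 in high male 7, and between -0.12 and 0.10 in the control libraries. The library labelled control male 6 read 1.98 for Xist, the RNA of the inactive X chromosome, and -2.11 for the Y-linked gene Ddx3y, both inside the range of the 9 female libraries. Libraries of high females also lay farther from each other than control females did, with a mean distance of 0.50 (6 pairs) against 0.24 (10 pairs), a difference of 0.26 (exact permutation test, 2-sided, 126 splits, p = 0.0159). In males the distances were 0.25 and 0.20 (exact permutation test, p = 0.127). Both tests exchange pups across slides and so disregard slide.

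**Figure D1:**
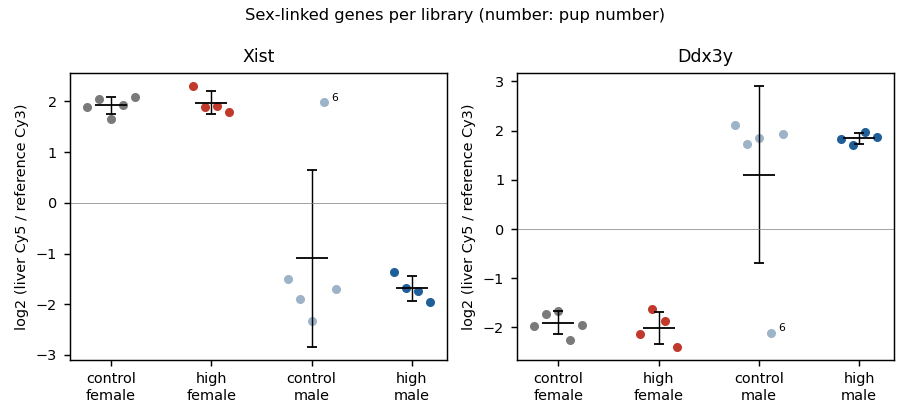
Log2 ratio of liver over reference for Xist and Ddx3y in each library (points), with group mean and SD (black), for control females (n = 5), high females (n = 4), control males (n = 5) and high males (n = 4). The library labelled control male 6 lies with the females at 1.98 for Xist and -2.11 for Ddx3y.

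The comparison of female pups asked whether maternal carbon black changed expression in the newborn liver. In the female livers 136 transcripts were higher and 173 lower after exposure, with a median size of 0.55 (log2). Fibin, a secreted factor of limb bud development, rose 5.2-fold (log2 2.38 ± 0.55 SE, n = 5 and 4, adjusted p = 0.0488). Hkdc1, a hexokinase family member, rose by 2.01 ± 0.45 and Cyp2s1, a cytochrome P450, by 1.45 ± 0.27 (adjusted p = 0.0469 and 0.0343). Fn3k, which removes sugar adducts from proteins, fell by 1.56 ± 0.34, and Inhbb, a subunit of activin B, fell by 1.44 ± 0.35 (log2). The interferon-inducible GTPases Iigp1 and Ifi47 fell by 1.39 ± 0.33 and 1.22 ± 0.23. These SEs and p values use 1 spread shared by all groups. The SD of Fibin was 1.82 in high females and 0.30 to 0.47 in the other groups. That of Hkdc1 was 1.55 against 0.17 to 0.30. Where exposed females varied more, the shared spread gives SEs and p values that are too small.

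The other higher genes among the 24 named were Galnt15 (1.62), Sparcl1, a matrix glycoprotein (1.54), Sycn, a protein of pancreatic zymogen granules (1.44), Cbr3, a carbonyl reductase (1.30), Il17d (1.19), Cys1 (1.18), Pmp22 (1.16), Gpx3, the extracellular glutathione peroxidase (1.13), and Kcne3 (1.08). The other lower genes were the protease Ctse (-1.29), Fabp12 (-0.97), Snx22 (-0.97), the MYC network member Mxd3 (-0.92), the DNA glycosylase Neil3 (-0.91), the nucleoside kinase Dck (-0.88), the red cell urea transporter Slc14a1 (-0.88) and Zfp367 (-0.87). Of the 24, all but Cbr3 (3 of 4) moved the same way on 4 of the 4 slides that held females of both exposures. The genes were picked from these same libraries for large differences, so this agreement is largely set by the choice. The sizes of many of the larger values rested on few pups. Hkdc1 read 5.31 in high female 13 and 2.03 to 2.77 in the other exposed females, all above the control females (0.73 to 1.19). Inhbb read -1.51 in high female 13, -1.45 in high female 6, and 0.16 and 0.53 in the others. Sparcl1 read 4.87 and 4.50 in high females 13 and 8, the libraries with raised pancreas genes, and 2.24 and 3.01 in high females 4 and 6. Without high female 13, the Hkdc1 difference was 1.26 and still passed, while that of Slc14a1 was -0.56 and no longer passed. Without high females 6 and 13 Fibin stood at 0.96, Gpx3 at 0.49, Inhbb at -0.53 and Iigp1 at -0.49, and without high females 8 and 13 Sparcl1 stood at 0.51 and Sycn at 0.69, none of them past the threshold.

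**Figure D2:**
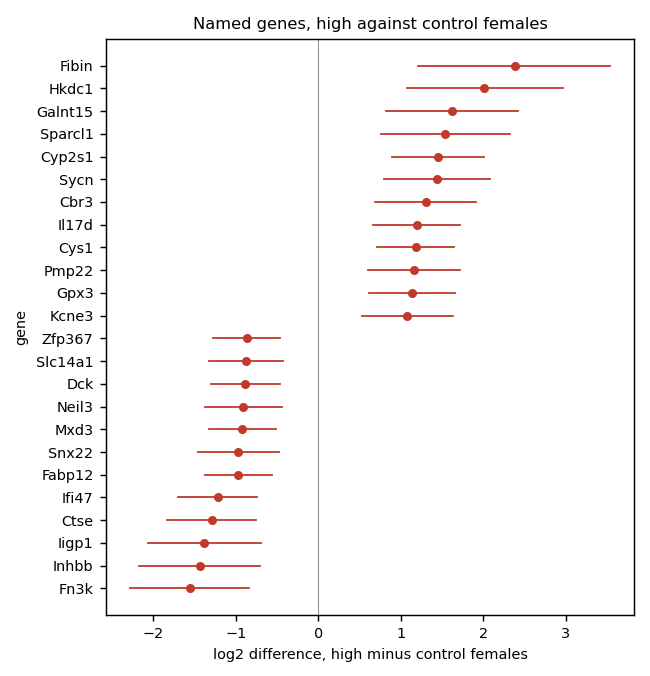
Log2 difference of high minus control females for the 24 named genes (points) with 95% confidence intervals (lines), 4 against 5 libraries. The intervals use the spread shared by all groups and are too narrow where high females varied more. The values run from -1.56 (Fn3k) to 2.38 (Fibin).

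Of the 309 transcripts past the threshold in females, 89 higher and 130 lower ones were named genes. A total of 4815 transcripts had an unadjusted p under 0.05, against 1053 expected by chance. With slide as a block 325 transcripts passed, of which 211 were shared with the 309. Of the named genes, Hkdc1 (2.00, adjusted p = 0.0519), Sparcl1 (1.49, adjusted p = 0.0523), Inhbb (-1.44, adjusted p = 0.054) and Iigp1 (-1.38, adjusted p = 0.0511) did not pass with slide as a block. The count was not stable to the choice of libraries. It was 0 without control female 2, 8 or 11 or control male 1 or 5, each left out alone. It was 7 without high female 13, 32 without high male 5, 41 without control male 3, 51 without control male 7, 53 without high male 9, 55 without control male 6, 67 without high male 14, 96 without control female 4 and 114 without high male 7. It rose to 506 without high female 6, 2335 without high female 8 and 2398 without high female 4. With only the 9 female arrays in the fit, or with array weights, limma called 0. None of the 24 named genes passed in all 18 of these fits, and they passed in 2 to 12 of them. Median centring in place of loess gave 147 higher and 6 lower transcripts. Without the libraries with raised pancreas genes (high females 8 and 13) 470 passed, and without high females 6 and 13 only 6.

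Genes of cell division were lower in exposed females. Of 48 measured cell cycle genes, 47 lay below 0, 7 fell past the threshold over all genes, and 46 fell when adjusted over the list alone. E2f8 (-0.78 ± 0.14), Foxm1 (-0.53 ± 0.11) and Mybl2 (-0.76 ± 0.17), transcription factors of the cell cycle, and the thymidine kinase Tk1 (-0.66 ± 0.14) were among the 7. The list median was -0.66 (adjusted p = 1.25e-23; adjusted p = 0.633 with an estimated correlation). With the preset correlation, all 99 other random splits of the female arrays into groups of the same sizes also called at least 1 list. A small adjusted p of a list therefore does not by itself show an effect of exposure. High female 13 lay at -1.56 and the other 3 exposed females between -0.47 and -0.29, against -0.40 to 0.20 in control females. Without high female 13 the median was -0.385 and the list was still called. Within the 4 slides the differences were -0.54, -0.24, -0.46 and -1.09. With an estimated correlation 0 of the 49 lists were called in any comparison, and fry, which tests whether the members of a list move on balance in a single direction and does not compare them with other genes, also called 0 (smallest adjusted p = 0.0983, in females). Its mixed form, which tests for change in either direction, called 24 lists in females, 14 in exposed males against exposed females and 0 in the other comparisons.

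Red cell genes were lower as well. Of 29 erythroid genes 28 lay below 0, 0 passed over all genes (limma) and 18 fell when adjusted over the list alone, with values of -1.19 for the blood group protein Rhd, -1.09 for Hemgn and -0.54 for the embryonic globin Hbb-bh1. The erythroid median was -0.64 (adjusted p = 5.28e-09; adjusted p = 0.633 with an estimated correlation), and the differences within slides were -0.79, 0.48, -1.03 and -0.46. High female 6 did not share the lower level, at 0.05. Of 23 genes of heme and iron metabolism, the heme synthesis enzymes Alad (-0.80) and Uros (-0.85) fell and Bmp6, a regulator of iron balance, rose (0.36), while 20 did not pass. Adjusted over the list alone, 11 fell and 1 rose. The heme and iron median was -0.43 (adjusted p = 0.00159; adjusted p = 0.633 with an estimated correlation). It was -0.28 without high female 13, and the slides gave -0.48, 0.23, -0.61 and -0.23.

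Interferon-stimulated, cytokine and lymphoid genes were lower, while the granulocyte (median 0.055, adjusted p = 0.428), macrophage (-0.081, adjusted p = 0.069) and mast cell and basophil lists (-0.038, adjusted p = 0.62) were not called. All 27 interferon-stimulated genes measured lay below 0, with 1 past the threshold over all genes (Iigp1) and 20 lower when adjusted over the list alone, among them Psmb9, an immunoproteasome subunit (-0.94), Ifih1, an RNA sensor (-0.545), and Ifit3 (-0.76). The median was -0.46 (adjusted p = 3.64e-12; adjusted p = 0.633 with an estimated correlation), and the slides gave -0.42, -0.56, -0.65 and -0.68. Among 26 cytokine and chemokine genes, Ccl7 (-0.39) and Ifng (-0.62) fell, and 5 fell and 1 rose when adjusted over the list alone. The cytokine median was -0.22 (adjusted p = 0.000703; adjusted p = 0.633 with an estimated correlation). It was -0.08 without high females 6 and 13, which ended the call. Among 22 lymphoid genes the T cell kinase Lck (-0.555) and the granzyme Gzmb (-0.82) fell, and 5 fell when adjusted over the list alone. The lymphoid median was -0.115 (adjusted p = 0.00518; adjusted p = 0.703 with an estimated correlation), -0.175 without control female 11, -0.03 without control female 9 and -0.06 without high female 6.

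Complement and cholesterol genes were called lower on weaker ground. Of 35 complement and coagulation genes C1ra fell (-0.66), and 6 fell and 2 rose when adjusted over the list alone. The median was -0.09 (adjusted p = 0.00815; adjusted p = 0.703 with an estimated correlation). The call ended without control female 8 (0.05) or high female 6 (-0.05), and the median was -0.19 without control female 4, -0.06 without control female 9 and -0.15 without high female 4. None of 25 cholesterol synthesis genes passed, over all genes or adjusted over the list alone (limma, 0). Hmgcs1 read -1.04 ± 0.46 and the cholesterol median was -0.345 (adjusted p = 0.00573; adjusted p = 0.703 with an estimated correlation). It was -0.09 without high female 13, which ended the call, -0.53 without high female 4, and 0.36, -0.77, 0.13 and -1.08 within the slides.

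Respiratory chain and ribosomal protein genes were higher, while the fatty acid oxidation list was not called (median 0.011, adjusted p = 0.891). All 44 nuclear genes of the respiratory chain measured lay above 0. Atp5c1, an ATP synthase subunit, rose past the threshold over all genes (0.47 ± 0.11), and 32 rose when adjusted over the list alone, among them Atp5o (0.515), Cyc1 (0.65) and Cox6b1 (0.40). The median was 0.35 (adjusted p = 5.77e-17; adjusted p = 0.633 with an estimated correlation). High females 6 and 13 lay at 0.62 and 0.63, high female 4 at 0.22 and high female 8 at -0.0042, and the slides gave 0.20, 0.47, 0.09 and 0.59. Of 51 ribosomal protein genes, 49 lay above 0 and 4 rose when adjusted over the list alone, such as Rpl27 (0.255) and Rpl9 (0.26). The ribosomal median was 0.16 (adjusted p = 1.74e-08; adjusted p = 0.703 with an estimated correlation).

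Glucocorticoid-responsive and hypoxia-inducible genes were higher in few pups. Of 19 glucocorticoid-responsive genes, 6 rose and 1 fell when adjusted over the list alone and 0 passed over all genes (limma). The transcription factor Cebpd read 1.22 ± 0.32, the cell cycle inhibitor Cdkn1a 0.69 ± 0.19 and the chaperone Fkbp5 0.555 ± 0.17. The median was 0.57 (adjusted p = 8.14e-05; adjusted p = 0.633 with an estimated correlation). High females 6 and 13 lay at 1.05 and 1.15, high females 4 and 8 at -0.0037 and 0.09, and control females between -0.12 and 0.11. The median was 0.34 without high female 13 and 0.35 without high female 6. Without both it was 0.017 and the direction of the test turned. Of 19 hypoxia-inducible genes 1 rose when adjusted over the list alone, the glycolytic enzyme Pgk1 (0.80). The hypoxia median was 0.29 (adjusted p = 0.00421; adjusted p = 0.703 with an estimated correlation) and 0.03 without high female 6, which ended the call. That library lay at 1.23.

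Among 20 glycolysis genes 4 rose and 1 fell when adjusted over the list alone, including Ldhb (0.85) and Pgam1 (0.89). The median was 0.29 (adjusted p = 0.00919; adjusted p = 0.703 with an estimated correlation), and without high female 6 it was 0.09 and the call ended. Among 19 gluconeogenesis genes Foxo1, a regulator of glucose output, rose (0.57) and so did Gpt2 (0.51), each adjusted over the list alone. The gluconeogenesis median was 0.25 (adjusted p = 0.0137; adjusted p = 0.633 with an estimated correlation). The call ended without high female 6 (0.14), without control female 4 (0.31) or with scale normalization (0.16), and the median was 0.39 without high female 8. None of 35 genes of amino acid and urea metabolism passed in limma, over all genes or adjusted over the list alone (0), and the list median of 0.14 turned to -0.035 with scale normalization (adjusted p = 0.0233; adjusted p = 0.703 with an estimated correlation). The call also ended without control female 2 (0.11), control female 4 (0.15), control female 9 (0.12), high female 6 (0.12) or high female 13 (0.09), and the median was 0.24 without high female 8.

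Matrix, bile duct, pancreas and gut genes were called higher in exposed females. Of the other lists of neighbouring or distant tissue, muscle (adjusted p = 0.661), adrenal, kidney and adipose (adjusted p = 0.111), lung (adjusted p = 0.891) and skin genes (adjusted p = 0.443) were not called. Of 32 genes of stellate cells, fibroblasts and matrix 6 rose when adjusted over the list alone, such as the smooth muscle protein Tagln (1.15) and the proteoglycan Dcn (0.70). The median was 0.435 (adjusted p = 3.21e-05; adjusted p = 0.703 with an estimated correlation). High female 8 lay at 1.05, and without it the median was 0.18 and the call ended. Of 16 bile duct and progenitor genes 2 rose and 1 fell when adjusted over the list alone, with Krt19, a duct keratin, at 1.25. That median was 0.30 (adjusted p = 0.0071; adjusted p = 0.633 with an estimated correlation), and 0.17 without high female 8, which ended the call. Of 17 exocrine pancreas genes Sycn passed over all genes and 14 rose when adjusted over the list alone. The pancreas median was 1.37 (adjusted p = 1.73e-06; adjusted p = 0.633 with an estimated correlation). It was 0.75 without high female 8, and -0.08 without high females 8 and 13, which ended the call. None of 14 gut and stomach genes passed in limma, over all genes or over the list alone (0), and their median was 0.30 (adjusted p = 0.0473; adjusted p = 0.703 with an estimated correlation). High female 13 lay at 1.53, and without it the gut median was 0.03. The gut call also ended without control female 2 (0.29), 4 (0.33) or 9 (0.33) or high female 4 (0.32), and, at an unchanged 0.30, without control male 1, 6 or 7 or high male 5, 7, 9 or 14. It stayed without high female 6 (0.49) or 8 (0.47).

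**Figure D3:**
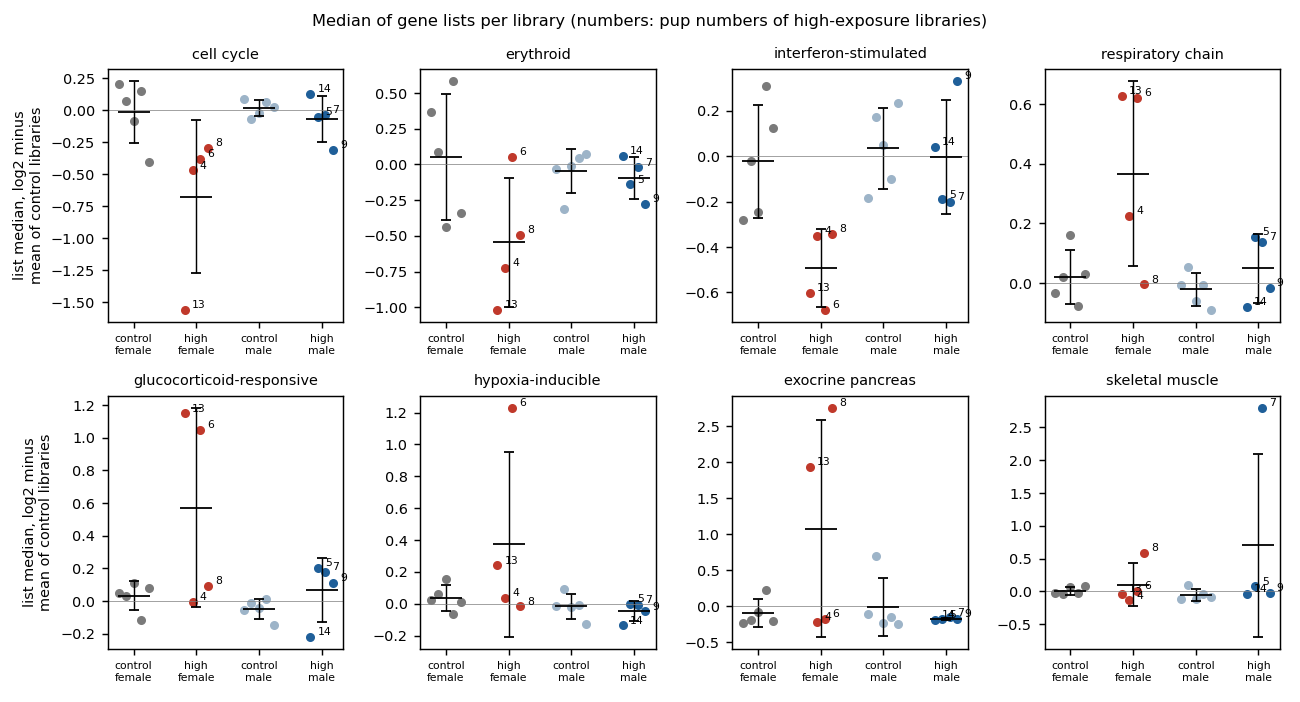
Median of the members of 8 gene lists in each library, in log2 after subtracting the mean of the control libraries (points; numbers are pup numbers), with group mean and SD (black). Cell cycle genes lie at -1.56 in high female 13, glucocorticoid-responsive genes at 1.05 and 1.15 in high females 6 and 13, pancreas genes at 2.76 and 1.94 in high females 8 and 13, and muscle genes at 2.80 in high male 7.

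The lists of NRF2 targets, aryl hydrocarbon receptor targets, acute phase genes and antioxidant enzymes were not called in females. Among 26 NRF2 target genes Me1 (0.62), Cbr3 (1.30) and Ugdh (0.84) rose, while Gclc, a subunit of the enzyme that starts glutathione synthesis, read -0.63 (adjusted p = 0.056). The NRF2 median was 0.010 (adjusted p = 0.891). Among 11 aryl hydrocarbon receptor targets 0 passed in limma, over all genes or adjusted over the list alone, with Cyp1a2 at -0.90 ± 0.29 (adjusted p = 0.0892) and a median of 0.0025 (adjusted p = 0.873). Among 31 acute phase genes Cd14, a lipopolysaccharide receptor, rose (0.54 ± 0.12), Saa4 read -0.83 (adjusted p = 0.0535) and the median was 0.033 (adjusted p = 0.958). Among 19 antioxidant enzymes Gpx3 rose and the median was 0.034 (adjusted p = 0.62).

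In male livers no transcript passed the threshold in limma (0 of 21062), and 356 had an unadjusted p under 0.05 against 1053 expected. These tests use the spread shared with the high females. Where high females varied more than males, the SEs and p values in males are too large. The lack of calls therefore does not show that males did not respond. The control males include library 6, whose Xist and Y-linked genes lay in the female range, and the count was 0 without it and without each of the other 17 libraries. The 20 genes with the smallest p are given as values. Phospholamban, Pln, a calcium regulator of heart and slow muscle, had the largest of these at 0.81 ± 0.20 (adjusted p = 1). Pln was well above background in 1 of 5 control males and 4 of 4 high males, so the size of its difference depends on the background. The insulin receptor Insr read 0.25 ± 0.065, the gut peptide Nts 0.575 ± 0.20, and the muscle genes Cacng1 and Stac3 0.49 ± 0.155 and 0.42 ± 0.13, each with adjusted p = 1. The others among the 20 lay between -0.27 (Gimap3) and 0.52 (Lingo4).

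Of the gene lists, 5 were called in males. All 17 muscle genes lay above 0 with a median of 0.795 (adjusted p = 1.96e-09; adjusted p = 0.982 with an estimated correlation). High male 7 held this value: without it the muscle median was 0.029, the direction of the test turned, and the slide differences were 0.14, 0.19, 2.80 and 0.055. Cholesterol synthesis genes had a median of 0.18 (adjusted p = 0.00639; adjusted p = 0.982 with an estimated correlation), with 24 of 25 above 0. It was 0.12 without control male 6 and 0.069 without high male 7, each of which ended the call, 0.30 without control male 7 and 0.295 without high male 14. With slide as a block the cholesterol median was 0.105 and the list was not called (adjusted p = 0.418). Cell cycle genes had a median of -0.070 (adjusted p = 0.0215; adjusted p = 0.982 with an estimated correlation), which was -0.039 without control male 1 and 0.0091 without high male 9, both ending the call, and -0.14 without high male 14. Granulocyte genes lay at 0.11 but at -0.057 with scale normalization (adjusted p = 0.0219; adjusted p = 0.982 with an estimated correlation). The granulocyte call ended without control male 3 (0.035), high male 5 (0.13) or high male 9 (0.048), and the median was 0.195 without high male 14. Ribosomal protein genes lay at 0.059 (adjusted p = 0.0219; adjusted p = 0.982 with an estimated correlation), and their call ended without control male 5 (0.033) or high male 5 (0.038) and turned without control male 7 (-0.0012) or high male 7 (-0.0012). Their median was 0.11 without high male 14. No member of the 5 lists passed in limma, over all genes or adjusted over the list alone (0). The number of lists called was 8 without control male 3, 9 without high male 14 and 3 without high male 7, and 10 with slide as a block, of which 4 were among the 5.

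Averaged over both sexes, 0 transcripts passed in limma, while 2868 had an unadjusted p under 0.05 against 1053 expected. The count was 126 without high female 4, 2 without high females 8 and 13 and 1 without high females 6 and 13. The smallest p values belonged to Gzmb, a granzyme of cytotoxic lymphocytes (-0.58 ± 0.105, adjusted p = 0.281, the same direction in 7 of 8 slide differences), and Hhip, a hedgehog-binding protein (0.34 ± 0.063, adjusted p = 0.281, 8 of 8). The T cell kinase Lck read -0.30, the amino acid transporter Slc7a5 -0.21, the coagulation factor gene F13a1 0.52, Cd14 0.365, the signalling kinase Irak2 -0.285 and the chitinase-like gene Chil4 0.655, each with adjusted p = 0.281. Of the 49 lists, 22 were called, 14 higher and 8 lower. Some of these calls were unstable over the 18 fits with 1 library left out. The circadian call ended in 10, the granulocyte and macrophage calls in 7 each, the complement call in 6 and the hypoxia call in 4. The calls of the cell cycle, interferon, respiratory chain and erythroid lists ended in 0. Cell cycle genes had a median of -0.37 (adjusted p = 4.29e-24; adjusted p = 0.628 with an estimated correlation), which was -0.225 without high female 13, and 31 of them fell when adjusted over the list alone. Interferon-stimulated genes lay at -0.235 (adjusted p = 1.86e-11; adjusted p = 0.628 with an estimated correlation). Respiratory chain genes lay at 0.20 (adjusted p = 1.49e-16; adjusted p = 0.628 with an estimated correlation), and 19 rose when adjusted over the list alone. Erythroid genes lay at -0.31 (adjusted p = 4.72e-09; adjusted p = 0.629 with an estimated correlation). With slide as a block 0 transcripts passed and 21 lists were called, 20 of them shared.

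**Figure D4:**
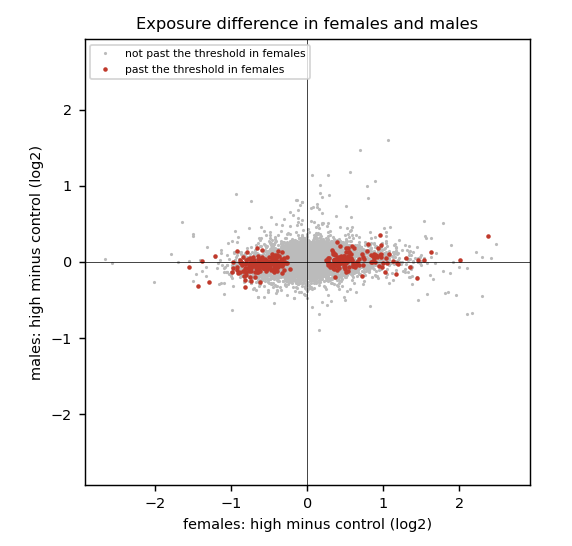
Exposure difference of each transcript in males (vertical axis) against that in females (horizontal axis), both high minus control in log2, with the 309 transcripts past the threshold in females in red. The red points lie far from 0 in females (median size 0.55), which their selection in females sets, and near 0 in males (median 0.022 in the female direction). The contrast is therefore no test of a difference between the sexes.

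The difference of the exposure effect between the sexes was tested itself, since a call in females alone does not show that the sexes differ. No transcript passed in limma (0), and 2114 had an unadjusted p under 0.05 against 1053 expected. The count was 57 without high female 4, and 1 without control male 6, high females 8 and 13 and high male 7 together. The smallest p values belonged to Bmp6 (0.56 ± 0.12), Tax1bp3 (0.44 ± 0.096), Cpne7 (0.46 ± 0.10), Slc7a5 (-0.39 ± 0.087), Fbxw4 (-0.42 ± 0.095) and Fnbp1l (0.61 ± 0.14), each with adjusted p = 0.488. Bmp6 stood at 0.36 in females, and its means were 0.78 in control and 0.58 in exposed males. Of the 309 transcripts past the threshold in females, 204 (66%) had the same direction in males, with a median of 0.022 against 0.55 in females. They were selected by their female difference, so a smaller value in males follows in part from the selection. Across all transcripts, which are not independent replicates, the female and male differences correlated at 0.136. Of the 49 lists 16 were called as different between the sexes, 8 in each direction, and 18 with slide as a block. For cell cycle genes the median difference of the exposure effect, female minus male, was -0.61 (adjusted p = 8.65e-17; adjusted p = 0.765 with an estimated correlation), -0.31 without high female 13. Interferon-stimulated genes differed by -0.45 (adjusted p = 3.75e-09; adjusted p = 0.765 with an estimated correlation). Respiratory chain genes differed by 0.28 (adjusted p = 4.94e-12; adjusted p = 0.765 with an estimated correlation), 0.17 without high female 13, and 0.015 without high females 6 and 13, which ended the call. Pancreas genes differed by 1.55 (adjusted p = 1.71e-07; adjusted p = 0.765 with an estimated correlation), 0.85 without high female 8, and 0.19 without high females 8 and 13, which ended the call.

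Male and female pups were compared as a check of the sex labels and to describe sex differences. Each control labelled male lay in position 1 and each control female in position 2. Sex differences in controls therefore cannot be told apart from array position. In the exposed pups 7 transcripts passed, 3 higher and 4 lower in males, and 3998 had an unadjusted p under 0.05 against 1053 expected. The named ones were the Y-linked genes Eif2s3y (4.30 ± 0.67), Ddx3y (3.85 ± 0.63) and Kdm5d (1.08 ± 0.18), and Xist (-3.67 ± 0.60), each with adjusted p = 0.0354 (n = 4 and 4). In the exposed pups these genes were well above background in no library of the sex with the lower level, so the sizes of these differences depend on the background, and no folds are given. Of the X-linked genes that escape inactivation, Kdm5c (-0.27), Kdm6a (-0.43), Eif2s3x (-0.37, but 0.19 when the probes of a gene were averaged) and Ddx3x (-0.34) did not pass. The count of 7 became 0 without control female 2, 4, 8, 9 or 11, control male 1, high female 6, or high male 5, 7 or 9, each left out alone, and 0 with slide as a block. It was 1 without control male 3 or 7, 2 without high female 13, 4 without high male 14, 1079 without high female 4 and 1372 without high female 8. Of the lists 19 were called, 8 higher in males and 11 lower, and the cell cycle median was 0.62 (adjusted p = 2.9e-21; adjusted p = 0.622 with an estimated correlation), 0.33 without high female 13.

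In control pups 0 transcripts passed in limma, and 311 had an unadjusted p under 0.05 against 1053 expected. These p values also use the shared spread and are too large where high females varied more than controls. Xist read -3.01 ± 0.54 (adjusted p = 0.165), Eif2s3y 3.35 ± 0.60 (adjusted p = 0.165), Ddx3y 3.01 ± 0.56 (adjusted p = 0.202) and Kdm5d 0.725 ± 0.16 (adjusted p = 0.689). In control females Eif2s3y and Kdm5d were well above background in 0 of 5 libraries and Ddx3y in 1 of 5, and in control males Xist was in 2 of 5, so the sizes of these 4 differences depend on the background. Without the library labelled control male 6, 10 transcripts passed, 4 higher and 6 lower in males, and Xist read -3.78, Eif2s3y 4.23, Ddx3y 3.81 and Kdm5d 0.93. The X-linked genes Kdm5c (-0.29), Kdm6a (-0.44), Eif2s3x (-0.40, but 0.11 when the probes of a gene were averaged) and Ddx3x (-0.089, but 0.011 with median centring) had adjusted p = 1. Of the lists 6 were called, with 3 without control female 11, 10 without control female 9 or control male 7, and 11 without control female 4 or control male 6. Platelet and megakaryocyte genes, all 15 below 0, had a median of -0.12 in males against females (adjusted p = 0.00013; adjusted p = 0.961 with an estimated correlation), -0.068 without control female 2 and -0.19 without control female 4.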

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

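The tests of tissue genes in single libraries, of control male 6 and of high female 13 were chosen only after the result was seen. Predictions for blood-forming cells, and for neighbouring tissue as the whole cause of the female lists, were written before those tests were run. Both start from patterns already seen in the data, and leaving out high females 8 and 13 was chosen after seeing the data.

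The library labelled control male 6 carried the sex-linked expression of a female. Xist read 1.98 (other males -2.34 to -1.36), Ddx3y -2.11 (1.70 to 2.11), Eif2s3y -1.76 (2.40 to 2.83) and Kdm5d -0.775 (0.11 to 0.445), so 4 of these 4 genes lay in the female range, consistent with a wrong sex label or an exchange with a sample outside the series. A swap with a female library of this series was excluded, since 0 libraries labelled female had a Y-linked gene in the male range. The same library also stood apart from the other control males for Ddx3x (0.335), Pln (0.39) and Ctse (2.91). Without it 10 transcripts passed in control males against control females, where Xist moved from -3.01 to -3.78, and 55 passed in exposed females, whose fit shares its estimate of the spread with the males.

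Genes of neighbouring tissue were raised in single exposed libraries. Of 17 pancreas genes 88.2% exceeded the highest control library in high female 8 and 88.2% in high female 13. Of 17 muscle genes 100% did so in high male 7 (list median 2.8). RNA of pancreas or muscle in these liver samples would give such values, but the libraries were picked for their high list medians, so the shares restate that pattern. Of the 5 brightest pancreas genes 4 exceeded the highest control in each of high females 8 and 13. The brightest, Amy2a5, stood only 0.28 and 0.256 above the control mean. For gut genes in high female 13 (71.4%, median 1.53) and muscle genes in high female 8 (70.6%) the test left this open. Pancreas genes were also at 0.693 in control male 3, apart from the other control males, so the signal is not limited to exposed pups. Without high females 8 and 13, 14 of the 17 other lists were still called in the same direction. That count alone cannot exclude neighbouring tissue as the whole cause of the female lists, since the list test called lists in all 99 other splits of the female arrays. High females 4 and 6 had no raised pancreas (-0.212 and -0.175), gut (0.03 and 0.01) or muscle medians (-0.14 and 0.005). Both lay outside the control females for interferon (-0.35 and -0.68, against -0.28 to 0.31) and respiratory chain genes (0.22 and 0.62, against -0.08 to 0.16). For cell cycle and erythroid genes only high female 4 did. For the first lists in these libraries, this argues against RNA of pancreas, gut or muscle as the whole cause.

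The lower cell cycle genes in exposed females may reflect fewer blood-forming cells, which still occupy the newborn liver. Over the 10 control libraries the cell cycle and erythroid medians correlated at r = 0.762 (permutation p = 0.0084, adjusted 0.0084 over both relations; rho = 0.842, p = 0.0036), and at 0.839 without the 2 libraries farthest from the median. Over all 18 libraries r was 0.808 (permutation p = 4e-05, adjusted 8e-05; rho = 0.827, p = 2e-05) and 0.671 without 2 libraries. The permutations disregard exposure, sex and slide, and the lower level of both lists in high females would itself give a correlation here. The 10 control libraries are among the 18, so both relations overlap. Other causes that move both lists would give such a correlation too, and high female 6 goes against this explanation, with cell cycle genes at -0.376 but erythroid genes at 0.0544 and slide differences of -0.24 and 0.478. High female 13 lay at -1.56, and whether it alone makes the difference cannot be told apart, since the other 3 exposed females averaged -0.379, 1 of them below the lowest control female (-0.401), while the list was still called without it.

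Single libraries far from the rest of their group were searched for in 317 groups of values. The search found 27 such values, against 15.8 expected by chance, about 1 in 20 groups, and 7 of them came from control male 6 and 4 from control male 3. Among genes, Fibin read -0.993 in control female 11, Il17d 0.55 in high female 4 and Cys1 0.366 in control female 4. Kdm6a read 0.449 in control female 4, Kdm5d -0.563 in high female 4, Eif2s3x -0.611 in high female 13 and Fbxw4 -0.619 in high female 8. In males Insr read 0.394 in control male 5, Oaz3 0.102 and Olfr374 0.0203 in control male 7, and Ptprt -0.172 in high male 5. Among lists, immediate early genes lay at 0.193 in control female 9 and 0.184 in control male 3, heme and iron genes at -0.116 and erythroid genes at -0.314 in control male 3, and granulocyte genes at -0.366 in control female 4. No cause of these values was tested.

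By the test of the difference between the sexes, 16 lists differed in their exposure effect (female minus male), 0 of them with an estimated correlation (adjusted p = 0.765 to 0.872). Lower in females were cell cycle (-0.61), cholesterol synthesis (-0.545), erythroid (-0.541), interferon (-0.45), heme and iron (-0.4), cytokine (-0.26), complement (-0.16) and lymphoid genes (-0.133). Higher were pancreas (1.55), glucocorticoid (0.464), stellate and matrix (0.36), bile duct (0.315), glycolysis (0.295), respiratory chain (0.279), hypoxia (0.272) and ribosomal protein genes (0.116). Several calls ended without 1 library: hypoxia and glycolysis genes without high female 6 (0.061 and 0.034), glycolysis genes without high male 14 (0.25), matrix and bile duct genes without high female 8 (0.094 and 0.15), bile duct genes without control female 2 (0.28; the call stayed at 0.16 without high female 13 and 0.20 without high male 14), and glucocorticoid genes without high female 13 (0.20) or high female 6 (0.29). The cholesterol value was -0.26 without high female 13 and its call stayed, but the call ended without high females 6 and 13 (-0.068) and without control male 6, high females 8 and 13 and high male 7 together (-0.18). Calls also stayed for hypoxia genes without high female 8 (0.42), for matrix genes without high female 4 (0.54), for ribosomal protein genes without control female 11 (0.070) or high male 14 (0.066), for cell cycle and respiratory chain genes without high female 13 (-0.31 and 0.17) and for pancreas genes without high female 8 (0.85). Without high females 6 and 13 the calls of respiratory chain (0.015) and cytokine genes (-0.13) ended, and without high females 8 and 13 those of pancreas (0.19) and bile duct genes (-0.041) ended. The complement call ended without control female 8 (-0.046), control male 3 (-0.10), high female 6 (-0.12), high male 14 (-0.13) or high male 9 (-0.10), and stayed without control female 4 (-0.25). The heme and iron call ended without control female 8 (-0.34), high female 4 (-0.37), high female 8 (-0.35) or high male 14 (-0.31). The lymphoid call ended without control female 8 (-0.10) or 9 (-0.063), control male 3 (-0.15), 5 (-0.12) or 6 (-0.11), high female 4 (-0.11) or 6 (-0.094), or high male 14 (-0.089) or 9 (-0.14), and stayed without control female 11 (-0.23) or 2 (-0.21) or high male 7 (-0.23). Splits of the arrays into groups of the same sizes gave at least 16 lists in 47 of 100, with a highest other count of 27, so chance could not be excluded for the number of lists.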

How the results depend on the processing

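The number of transcripts past the threshold in exposed females depended strongly on the settings. The smallest adjusted p in limma was 0.0317, so all 309 calls lay close to the threshold of 0.05. Small changes in p can therefore add or remove many calls. What in each setting moved the p values was not tested. The count was 71 from the Agilent ratios, 140 from Cy5 alone, 153 with median centring, 917 with scale normalization, 53 without the filter on dim probes, 0 with only the groups compared and 0 with array weights. It was 1884 at adjusted p 0.10, 948 at unadjusted p 0.05 with a 1.5-fold difference, 1066 with slide as a random block (correlation 0.121) and 690 with the pup number as a random block. Over 6 pairs of a control and a high library with the same pup number the correlations ran from -0.182 to 0.473. The labels state no link between such pairs, and these values cannot show what the number means. Counts of 208 to 459 came from the authors' table, no background correction, offset 16, trend and robust variance, well above background on all arrays, and other probe rules. Leaving out each library gave 0 to 2398. The 24 named female genes kept their direction in all settings run, while 515 of their 1031 values lost the call. Among values not past the threshold, the sign changed for Itpripl2 (-0.156 from the Agilent ratios) and Olfr456 (-0.107 from Cy5 alone) in males, and for Ddx3x and Eif2s3x in the sex comparisons. Medians over all transcripts moved by under 0.1 in log2 with any scaling. Signals near background limit what small differences can show.

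For the other gene counts, the threshold of unadjusted p 0.05 with a 1.5-fold difference gave 8 in males, 89 over both sexes, 561 for the difference between the sexes, 11 for males against females in controls and 771 in exposed pups. Leaving out each library gave 0 to 126 over both sexes, 0 to 57 for the difference, 0 to 10 in controls and 0 to 1372 in exposed pups. The 7 transcripts of exposed males against exposed females became 108 at adjusted p 0.10, 14 with slide as a random block, 1 with trend and robust variance, and 0 with array weights, no filter on dim probes, the pup number as a block, slide as a fixed block, scale normalization, or probes well above background on all arrays.

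Of the alternatives chosen after seeing the data, leaving out high females 8 and 13 gave 470 transcripts in females, 2 over both sexes and 101 for exposed males against females. Leaving out high females 6 and 13 gave 6, 1 and 0. Leaving out high male 7 and control male 6 gave 0 in females and 10 for control males against females. Leaving out all of control male 6, high females 8 and 13 and high male 7 gave 236 in females, 1 for the difference, 10 in controls and 54 in exposed pups.

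With an estimated correlation 0 lists were called in females, males, both sexes, the difference between the sexes, and males against females in controls and in exposed pups, and fry called 0 in each of these 6, while its mixed form called 24 in females and 14 in exposed males against females. List tests were not run with random blocks or with the p-and-fold threshold, and within-slide differences give no counts. Lists called in females numbered 13 to 26 under the other settings. In males the 5 lists became 2 with Agilent ratios, 9 at adjusted p 0.10, 10 with array weights, every probe on its own, median centring, only the groups compared or slide as a fixed block, 3 with offset 16, 19 with scale normalization and 11 with probes well above background on all arrays. They became 10 without high females 8 and 13, 9 without high females 6 and 13, 2 without high male 7 and control male 6, and 3 to 9 with each library left out. For control males against females the 6 lists became 3 with Cy5 alone, 10 at adjusted p 0.10, 12 with median centring or only the groups compared, 13 without the 4 libraries, 11 without high females 6 and 13 or without high male 7 and control male 6, and 3 to 11 with each library left out. Without high females 6 and 13 there were 10 lists for the difference, 13 over both sexes and 11 for exposed males against females.

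Some lists turned direction in the test, and a few of these kept the sign of their median. With scale normalization amino acid and urea genes were at 0.00418 over both sexes and -0.0348 in females, and granulocyte genes at -0.117 over both sexes and -0.0572 in males. Without high females 8 and 13 the values were 0.0183 for bile duct, 0.0019 for gut and 0.142 for matrix genes in exposed males against females, -0.137 for pancreas genes over both sexes and -0.0621 for matrix genes in the difference. Without those 2, control male 6 and high male 7, bile duct genes were at -0.0773 and matrix genes at -0.0627 in the difference, bile duct genes at 0.0471, gut genes at 0.0342 and matrix genes at 0.142 in exposed males against females, pancreas genes at -0.162 and muscle genes at -0.0703 over both sexes, and cholesterol genes at 0.00151 in males. Without high male 7 and control male 6, cholesterol genes were at 0.00151 in males and muscle genes at -0.213 in exposed males against females.

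Without high females 6 and 13, cholesterol genes were at 0.139 in females and -0.0699 in exposed males against females. Glucocorticoid genes were at 0.0168 in females, -0.219 in the difference and 0.0306 in exposed males against females, and gluconeogenesis genes at 0.000368 in the last. Glycolysis genes were at 0.0109 in females and -0.0484 in the difference, and hypoxia genes at 0.0113 in females, 0.0121 over both sexes and -0.00488 in the difference. With each library left out, hypoxia genes over both sexes ran from 0.0245 to 0.24, muscle genes in males from 0.029 to 1.04 and in exposed males against females from -0.213 to 0.875, ribosomal protein genes in males from -0.0012 to 0.107, matrix genes in exposed males against females from -0.436 to 0.0286, and drug metabolism genes in control males against females from -0.14 to -0.0199. The mean within-slide difference of interferon genes in females was -0.577, against a median of -0.456.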

Other observations

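The splits that count lists in the sex comparisons and the split by scan day were chosen only after the result was seen, and the other splits and the test of the reference channel were written before.

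Beyond the lists called, several genes of exposed female livers stood out in lists that were not. In the Notch, Wnt and hedgehog list Hhip rose (0.51 ± 0.089 SE, adjusted p = 0.0317) and the Notch ligand Dll4 rose (0.41 ± 0.090, adjusted p = 0.0447), both in limma with n = 5 and 4. Of 24 genes of DNA methylation and chromatin 3 were lower when adjusted over the list alone: Uhrf1 (-1.08), Dnmt1 (-0.57) and Ezh2 (-0.50), which maintain chromatin marks in dividing cells. Of 21 macrophage and Kupffer cell genes 4 were lower when adjusted over the list alone, with Fcgr1 (-0.64) past the threshold over all genes, and the list was not called (adjusted p = 0.069). The fatty acid oxidation list was not called (adjusted p = 0.891), although Ucp2, a mitochondrial carrier, fell (-0.47 ± 0.10). Of 46 genes of drug metabolism Sult1c2 read -2.01 ± 0.51 and Ugt2b1 -0.69 ± 0.19, both lower when adjusted over the list alone. Among growth factor genes Igfals (-0.76) was lower and Igfbp3 (0.58) higher when adjusted over the list alone.

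The arrays were split at random into groups of the same sizes to see how often chance gives as many calls. In females 2 of the 100 splits gave at least 309 transcripts (real 309, highest other 391, 13 splits above 0), a share under 5%. These splits disregard slide, and the real count was itself 0 with only the female arrays in the fit, with array weights, and without control female 2, 8 or 11 or control male 1 or 5, so the share does not by itself rule out chance. As many as 19 lists came from 26 of 100 splits (highest other 26), so chance could not be excluded for the number of lists. In females and in each other comparison, every split besides the real one called at least 1 list (99 splits, and 34 in exposed pups). At least as many lists as in the real groups came from 89 of 100 splits in males (real 5, highest other 22), 7 of 100 over both sexes (real 22, highest other 29), 47 of 100 for the difference between the sexes (real 16, highest other 27), 90 of 100 for control males against females (real 6, highest other 20) and 7 of 35 for exposed males against females (real 19, highest other 23), so chance could not be excluded for these numbers of lists. Where the real groups gave 0 transcripts in limma, any split gives as many (100 of 100), so the splits test nothing there. The highest other counts were 1 in males, 1 over both sexes, 19 for the difference and 0 for control males against females. For exposed males against females 4 of 35 splits gave at least 7 transcripts (highest other 18), so chance was not excluded for the count by this test. The Xist and Y-linked genes among the 7 are a separate matter: Ddx3y ran from -2.39 to -1.63 in the 9 female libraries and from 1.70 to 2.11 in the 8 male libraries other than control male 6, without overlap.

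Females scanned on the last day (4) against the other females (5) gave 5 transcripts and 17 lists, nearly the number of lists of the exposure itself. The last-day females were control females 8 and 9 and high females 8 and 13, the exposed females with raised pancreas genes. Scan day therefore cannot be told apart from those libraries. Random splits gave at least 19 lists in 26 of 100, so 17 lists do not show an effect of scan day. The fit with slide as a block gave 325 transcripts and 20 lists in females. The reference channel argued against Cy3 differences of single genes as the cause of the female genes. Their median Cy3 difference was 1.03% of the ratio difference, and 0 transcripts passed in Cy3 in any comparison. Unadjusted limma p in Cy3 was under 0.05 for 344 transcripts in females and 1432 in males, against 1053 expected. The quantile normalization removes array-wide Cy3 differences, so these were not tested. Array medians of Cy3 were 76 to 82 in control females and 78.5 to 88 in high females. Array position was tied to exposure on each slide and to the labelled sex in controls, and no test here separates them. Litter and maternal effects were not tested, since the labels do not state which pups were littermates.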
